A study of Mus musculus with 7 samples.

How the data were processed

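Total RNA of paracardial and intra-abdominal fat from wild-type male mice was hybridised to Affymetrix arrays, with 4 paracardial and 3 intra-abdominal samples, per the labels. The authors deposited 1 log2 expression value per probe and array, made with RMA and Affymetrix Expression Console per the submitters' processing notes. Their versions, the background correction and the genome build are not given in the sources used here. The deposited values are taken as log2 from their range and the named method, while their scale, their centring and the reason for the ceiling stay unknown. Scanner files were not used here, so neither detection calls nor another background correction could be tried, and signal over background is unknown. Depth does not apply to arrays, and their number limits the precision. All 7 columns of the table were matched to samples by their sample names.

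Of 11949 probes, 9352 had exactly 1 gene symbol in the platform annotation given, 522 had several and 2075 had none. Symbols were updated through Entrez identifiers, of which those of 5789 probes matched the RefSeq table (assembly GRCm38.p6, used for names only), changing 188 symbols. For 52 genes with more than 1 probe, the probe with the highest mean over all arrays was kept, leaving 9294 genes. No probe was filtered for low signal. Probes with several symbols or none, 2597 in all, were left out of the gene tests. Of all probes, 635 shared all 7 values with another probe. A gene within 0.1 of an array's highest value was called at the ceiling, which held for 58 genes on all 4 paracardial arrays and 24 on all 3 intra-abdominal arrays. Such genes have only a bound and were left out of the ranking of genes, which changed no rank.

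Differences are paracardial minus intra-abdominal, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided) over all 7 arrays with no covariate, with 5 residual and 1.68 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and intervals are at 95%. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Of 43 lists fixed before the data were examined, 42 had a measured member, 31 had at least 5 and were tested, and 11 were only described. The erythroid list had no measured member. An exact permutation test of Adh1 used all 35 splits of the 7 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

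The rule for the genes named was also fixed before the data were examined. It took Adh1, and the 10 genes with the largest positive and the 10 with the largest negative difference among those past the threshold whose depots did not overlap. Unnamed gene models, olfactory and vomeronasal receptors, small RNAs and receptor segments of B and T cells were left out of that ranking by the form of their symbols, and Tcrg-C3, whose symbol has another form, stayed in. It also took up to 2 members of each list with the largest difference past the threshold, up to 8 for retinoid and alcohol metabolism, or the 1 largest member where none passed. It added Ucp1 and Wt1 whatever their test, and Wt1 was not analysed here. In all, 72 genes were named by the rule, of which 53 passed. Rag2, Tnc, H2ac10 and the genes of the added lists were named after their values were seen.

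The test was checked on simulated values for the 9294 genes of the depot comparison, with 200 genes changed. It recovered 48% of changes of 2 and 89% of changes of 4 on the log2 scale, with 0 wrong signs and 3 false calls. Simulated values with no change gave 0 genes and 0 lists, and a shift of the oxidative phosphorylation list by 1 was found. In the simulated depot comparison genes were drawn independently of each other, each with the same spread on all arrays. The measured values held 2265 genes at an unadjusted p under 0.05, far more than the 200 changed there. The shares recovered and the 3 false calls therefore hold for that setting and are not shown for the measured calls. In the measured values the estimated correlation within a list reached 0.867 (cell cycle), and another split of the arrays gave 20 lists. The simulation therefore does not show how often lists are called falsely in these data. Alternatives fixed before the data were examined were filters that dropped the dimmest 25% or 50% of genes, quantile normalization applied again, centring on array medians, cyclic loess, eBayes with trend and robust fitting, array weights, the replicate number as a block, the mean over a gene's probes, all probes, and each array left out in turn. Alternatives chosen after the data were seen were the array set as a block, only the 5 arrays of the lower ceiling, no paracardial arrays 1 and 2, and no genes at the ceiling. Lists of wider thymocyte, thymic epithelial and lymph node stromal genes were added after the data were seen.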

Results

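Gene expression was measured on Affymetrix microarrays in 2 fat depots of wild-type male mice. Paracardial fat (pCF), the fat beside the heart, was measured on 4 arrays and intra-abdominal fat (iVF) on 3 arrays. The labels call the samples of a depot biological replicates without saying whether each came from its own animal, so the p-values measure the spread between these samples. The deposited table holds 11949 probes with 1 log2 value per array, and 9294 genes were tested. The median value was 6.07, 6.005, 6.26 and 6.37 on paracardial arrays 1 to 4 and 6.12, 5.995 and 5.998 on intra-abdominal arrays 1 to 3. Values piled up at a ceiling between 19.8 and 19.9 on every array, where 0.711% to 3.23% of the probes lay within 0.1 of the highest value. The scale and its centring are therefore known only as far as the values show them, and differences below are on the deposited log2 scale, not calibrated folds. Paracardial array 4 and intra-abdominal array 3 shared the highest ceiling, 19.93, and the lowest 5th percentiles, 3.995 and 3.9996 against 4.38 to 4.44 on the other 5 arrays. These 2 arrays are called an array set here, the other 5 arrays the other set, and differences within each set are given below for some results. Across genes, which are not independent replicates, Pearson's r was 0.953 to 0.992 between paracardial arrays, 0.839 to 0.980 between intra-abdominal arrays and 0.809 to 0.958 between depots. Spearman's rho was 0.909 to 0.955, 0.8294 to 0.932 and 0.786 to 0.914 over the same pairs. The number of arrays limits the precision of every value.

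The comparison asked which genes differ between paracardial and intra-abdominal fat, and the series title names alcohol dehydrogenase 1 (Adh1) as the gene of interest. Adh1, which oxidises ethanol and retinol, was lower in paracardial fat. Its log2 value was 6.76 ± 1.14 (SD, n = 4) in paracardial fat and 11.37 ± 1.45 (SD, n = 3) in intra-abdominal fat, a difference of -4.61 with a standard error of 0.85 and a 95% confidence interval of -6.65 to -2.57. The limma adjusted p was 0.024, and all 4 paracardial arrays lay below all 3 intra-abdominal arrays. A two-sided exact permutation test gave p = 0.0286, the smallest value that 4 arrays against 3 can give. The difference was -4.03 within the set of 5 arrays and -5.52 within the set of 2. The adipocyte markers of the same arrays moved in the same direction, with medians of 6.08, 6.09, 9.02 and 9.64 on paracardial arrays 1 to 4 and 14.3, 14.7 and 16.0 on intra-abdominal arrays 1 to 3. Adh1 was no longer past the threshold without paracardial array 1 (adjusted p = 0.075), paracardial array 2 (0.055) or intra-abdominal array 2 (0.075), within the 5 arrays of the lower ceiling (0.053) and without paracardial arrays 1 and 2 together (0.142). Over all 20 alternatives its adjusted p ranged from 0.00079 to 0.142 and its difference from -5.47 to -3.72.

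Across all genes, 581 were higher and 270 lower in paracardial fat at an adjusted p under 0.05, 851 in all. Of all probes, 635 shared all 7 values with another probe and were not merged, so these counts may hold the same signal more than once. Ribosomal protein entries made up 79 of the 581, and 135 of the 156 measured entries of that family carry pseudogene symbols. The largest higher values belonged to genes of lymphocyte development, chromatin, cell division and epithelial keratins. They were led by Dntt (7.05 ± 1.48, difference ± SE, adjusted p = 0.034), the polymerase that adds nucleotides at antigen receptor joints, and the T cell receptor gamma gene Tcrg-C3 (6.57 ± 0.68, 0.0082). The histone genes H2ac15 (6.34), H2bu1-ps (5.70), H1f1 (5.59) and H1f5 (5.27), the mitotic kinesin Kif11 (5.36), the copy Pcna-ps2 of a replication factor gene (5.08) and the keratins Krt18 (6.06) and Krt8 (5.08) completed these 10. Copies of histone and Pcna genes are nearly identical in sequence, so the copy that gave the signal is uncertain. The 10 largest lower values were those of Aoc3 (-9.40 ± 0.89, adjusted p = 0.0082), an amine oxidase of adipocytes and vessels, Npr3 (-8.80), Lgals12 (-8.67), Prelp (-8.63), Serpina3n (-8.58), Fads3 (-8.56), leptin (Lep, -8.53 ± 0.91, 0.0082), Ehd2 (-8.50), the Wnt receptor Fzd4 (-8.46 ± 0.57, 0.0044) and the basement membrane protein Nid1 (-8.25).

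Of the 851 genes, 824 differed by at least 1 on the log2 scale, and in all 851 the arrays of the depots did not overlap. That alone fixes the same sign of the difference in both array sets, so the agreement of the sets is no separate support. Over all tested genes the depots did not overlap in 26.7%, where chance gives 5.71%. The histone H2ac10 lay at the ceiling on all 4 paracardial arrays, so its difference of 4.29 is a lower bound. The split of calls depended on the scaling, with 432 higher and 416 lower genes after quantile normalization was applied again and 512 higher and 530 lower after cyclic loess. The median difference over all genes was 0.133 as deposited and -0.0052 after the arrays were centred on their medians, which gave 573 higher and 340 lower genes. The count fell to 196 without paracardial array 1, 338 without array 2, 394 without array 3 and 185 without intra-abdominal array 2. Without intra-abdominal array 1 the higher genes fell from 581 to 378. Without paracardial arrays 1 and 2, an alternative chosen after the data were seen, 1 gene passed (Aoc3), with 1751 at an unadjusted p under 0.05. Within the set of 5 arrays 620 genes were higher and 316 lower, and with the array set as a block 1081 were higher and 573 lower. Without intra-abdominal array 2 the calls of Dntt (adjusted p = 0.134), H2ac15 (0.125), Kif11 (0.077), H1f5 (0.076) and Krt18 (0.055) also ended, those of Kif11 and H1f5 also without paracardial array 1. Dntt and H2ac15 were past the threshold in 1 of the 7 fits that left out an array, the one without intra-abdominal array 1.

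Genes of retinoid and alcohol metabolism were lower in paracardial fat as a list by the list test camera, though not with an estimated correlation (adjusted p = 0.00024 and 0.303). Of 12 measured genes, 5 were lower, none was higher and 7 did not pass (6 lower, adjusted over the list alone), with a median difference of -1.87 (-4.61 to -1.42 over 22 alternatives). Beside Adh1 these were the retinaldehyde dehydrogenase Aldh1a1 (-6.35 ± 1.11, adjusted p = 0.021), its near-identical paralog Aldh1a7 (-6.10 ± 1.17, 0.026), the plasma retinol carrier Rbp4 (-6.30 ± 1.13, 0.022) and retinol saturase, Retsat (-3.15 ± 0.26, 0.0067). The probes of Aldh1a1 and Aldh1a7 could share signal, so both values are uncertain. All 12 members had the same sign in both array sets, which the lack of overlap fixes for the 5 that passed. The adipocyte markers of the same arrays were lower too, with a median difference of -6.94, so the group is not shown to differ apart from them. Retsat was past the threshold whichever array was left out. Without intra-abdominal array 2 the adjusted p was 0.078 for Aldh1a1, 0.095 for Rbp4 and 0.089 for Aldh1a7. These 3 calls also ended without paracardial array 1 or 2, those of Rbp4 and Aldh1a7 without paracardial array 3, and that of Aldh1a7 without intra-abdominal array 3.

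**Figure D1:**
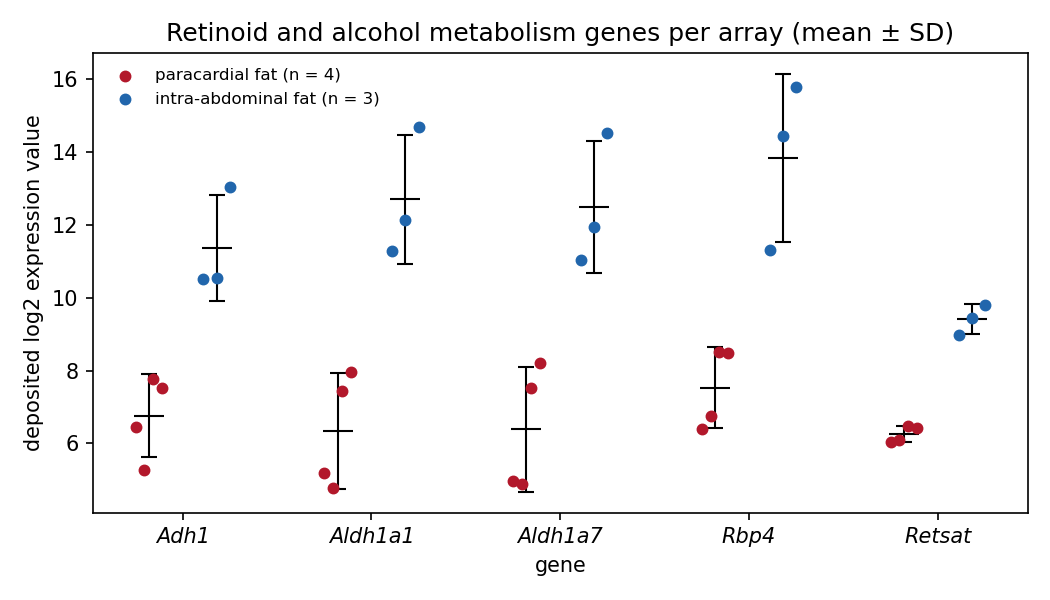
Deposited log2 values (y axis) of the 5 retinoid and alcohol metabolism genes that differed between depots (x axis). Red points are the 4 paracardial arrays, blue points the 3 intra-abdominal arrays, and black marks the mean ± SD; Adh1 averaged 6.76 in paracardial fat and 11.37 in intra-abdominal fat, and the arrays of the depots do not overlap in any of the 5 genes.

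Adipocyte markers and 4 lists of adipocyte functions were lower in paracardial fat by camera, and none of the 5 with an estimated correlation (adjusted p = 0.303 for each). Of 10 adipocyte markers 7 were lower and 3 did not pass (10 lower, adjusted over the list alone), with a median difference of -6.94, led by Lep and the droplet fusion protein Cidec (-7.61 ± 1.51, adjusted p = 0.029). Lipolysis and lipid droplet genes fell in 7 of 13 cases (8 adjusted over the list alone), led by the droplet coat protein Plin4 (-8.13 ± 0.81, 0.0082) and Cidec, with the glycerol channel Aqp7 (-7.35 ± 0.85, 0.0090) among them. Of 6 fatty acid and triglyceride synthesis genes 2 were lower (5 adjusted over the list alone), Agpat2 (-3.16 ± 0.67, 0.035) and the transcription factor Mlxipl (-1.19 ± 0.22, 0.024). Of 14 adipokines and secreted factors 4 were lower (6 adjusted over the list alone), led by Lep and Rbp4, and of 5 insulin signalling genes 2 were lower (4 adjusted over the list alone), the glucose transporter Slc2a4 (-2.45, 0.047) and the kinase subunit Pik3cb (-1.64, 0.033).

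Median differences of these lists were -3.48 for lipolysis, -3.99 for synthesis, -2.92 for adipokines and -1.64 for insulin signalling. Their camera adjusted p was 3.9e-10 for adipocyte markers, 8.4e-07 for lipolysis, 0.00024 for synthesis, 3.2e-06 for adipokines and 0.00032 for insulin signalling. Without intra-abdominal array 3 the adipokine median was -1.53, and it was -1.62 within the set of 5 arrays and -3.82 within the set of 2. The adipocyte medians differed by -7.09 within the set of 5 arrays and by -4.89 within the set of 2. The thymocyte markers ran the other way on the same arrays, with medians of 7.88, 7.79, 8.71 and 10.1 on paracardial arrays 1 to 4 and 7.68, 5.74 and 5.42 on intra-abdominal arrays 1 to 3. Aqp7 and Plin4 were past the threshold whichever array was left out. Without intra-abdominal array 2 the adjusted p was 0.105 for Cidec, 0.115 for Agpat2, 0.104 for Mlxipl, 0.129 for Slc2a4 and 0.091 for Pik3cb, and these calls also ended without paracardial array 1 or 2. Of the 7 fits that left out an array, Cidec, Agpat2 and Slc2a4 passed in 1, Pik3cb in 2 and Mlxipl in 3.

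Thermogenic genes, which mark brown fat, did not differ as a group. None of 9 passed (none adjusted over the list alone), and the list gave an adjusted p of 0.576, with a median of 0.25 while the test pointed to lower. Ucp1, the uncoupling protein of brown fat, differed by 2.83 ± 2.25 (adjusted p = 0.510), with values of 4.61, 4.99, 6.14 and 13.92 on paracardial arrays 1 to 4 and 4.84, 4.57 and 4.36 on intra-abdominal arrays 1 to 3. Without paracardial array 4 its difference was 0.66, and within the sets of 5 and 2 arrays it was 0.54 and 9.56. The list median turned to -0.30 without paracardial array 4. Of 5 beige fat markers 2 were lower (1 higher and 2 lower, adjusted over the list alone), Aqp7 and the fatty acid transporter Slc27a1 (-4.23 ± 0.45, 0.0082), genes of glycerol and fatty acid transport. Aqp7 is also one of the adipocyte markers. The list test pointed to lower (adjusted p = 0.035, mean -2.21, median -0.15; adjusted p = 0.303 with an estimated correlation). The median of the 5 markers was higher on every paracardial array (6.02, 5.98, 5.95 and 6.64) than on every intra-abdominal array (5.52, 5.21 and 5.63), so the list as a whole has no clear direction. Its median difference was -0.31 without paracardial array 2, -0.24, -0.25 and -0.10 without intra-abdominal arrays 1, 2 and 3, and -0.13 and -0.88 within the sets of 5 and 2 arrays. It lost the call without paracardial array 4 (0.058), without intra-abdominal array 3 (0.115), within the 5 arrays of the lower ceiling (0.187) and with the array set as a block (0.069).

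Fuel oxidation lists were lower in paracardial fat by camera but not by fry, mostly without single genes past the threshold. Of 12 fatty acid oxidation genes 1 was lower by the test over all genes (4 adjusted over the list alone), with a median of -1.40. It was Hadh, a beta-oxidation enzyme (-3.27 ± 0.78, adjusted p = 0.0499). No gene passed among 28 of oxidative phosphorylation (median -0.38; Sdhc -1.58, 0.057) or 6 of the TCA cycle (median -1.18; Cs -2.58, 0.137), over all genes or adjusted over the list alone. The list tests gave adjusted p = 1.5e-05 for fatty acid oxidation, 0.019 for oxidative phosphorylation and 0.0059 for the TCA cycle, and with an estimated correlation adjusted p = 0.371, 0.739 and 0.419. With fry none of the 3 passed (adjusted p = 0.104, 0.699 and 0.176). The adipocyte markers were lower by far more on the same arrays (median -6.94). Without intra-abdominal array 3 the medians were -0.82 for fatty acid oxidation, -0.034 for oxidative phosphorylation (adjusted p = 0.799) and -0.56 for the TCA cycle (0.104). The oxidative phosphorylation list, with a median of -0.61 without paracardial array 4, also lost its call without paracardial array 1 (0.093) or 2 (0.089) and within the 5 arrays of the lower ceiling (0.061). Without paracardial arrays 1 and 2 together this median turned to 0.11 (0.810). Hadh was past the threshold in 1 of 7 fits, the one without paracardial array 4, with 0.141 without intra-abdominal array 2. Of 10 cholesterol synthesis genes Hmgcs1 was lower (-3.93 ± 0.75, 0.025), the list adjusted p was 0.064 (median -0.39; 0.522 with fry), and the call of Hmgcs1 ended without intra-abdominal array 2 (0.083) and without paracardial arrays 1 to 3 each. Without intra-abdominal array 3 the cholesterol median was -0.029 (0.416). The cholesterol list passed without paracardial array 4 (0.035) or intra-abdominal array 1 (0.032) or 2 (0.023) and with the array set as a block (0.037). None of 6 glycolysis genes passed over all genes (1 lower, adjusted over the list alone; Ldhb 1.31, 0.280; list adjusted p = 0.762). Of creatine genes only Gamt was measured, at -0.87 (0.047), and it passed in 1 of the 7 fits that left out an array, with 0.170 without intra-abdominal array 2.

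T and NK cell markers and cell cycle genes were higher in paracardial fat as lists by camera (adjusted p = 0.405 and 0.303 with an estimated correlation), and the thymocyte list fell short of the threshold. Of 10 cell cycle genes 8 were higher and 2 did not pass (10 adjusted over the list alone), with a median difference of 3.43, led by Kif11 and the nucleotide reductase subunit Rrm2 (4.28 ± 0.79, adjusted p = 0.024). Of 8 T and NK cell markers 3 were higher (6 adjusted over the list alone), with a median of 3.73, among them the T cell receptor subunit Cd3d (4.09 ± 0.98, 0.0497) and the adaptor Lat (4.03 ± 0.90, 0.041). Of 6 genes of the thymocyte list 3 were higher (5 higher and 1 lower, adjusted over the list alone), with a median of 3.11. Among them were Dntt, Psmb11 (5.04 ± 1.11, 0.040) and Rag2, a recombinase gene named after its values were seen (4.65 ± 0.81, 0.021). Psmb11 encodes a proteasome subunit of cortical thymic epithelium, so it is not a gene of thymocytes although the list holds it. None of 11 B cell markers passed (none adjusted over the list alone; Jchain 2.54, 0.090), while the B cell list was higher by camera (median 0.59; adjusted p = 0.643 with an estimated correlation and 0.162 with fry).

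The list tests gave adjusted p = 8.4e-07 for cell cycle, 0.00095 for T and NK cells, 0.046 for B cells and 0.052 for thymocytes. With an estimated correlation they gave adjusted p = 0.303, 0.405, 0.643 and 0.504, and with fry adjusted p = 0.019, 0.047, 0.162 and 0.057. The thymocyte list passed in 8 of 21 alternatives, among them all 3 other scalings (adjusted p = 0.015 to 0.035) and the fits without paracardial array 1 (0.040), 2 (0.035) or 4 (0.035) or intra-abdominal array 1 (0.038). Cell cycle, T cell, B cell and thymocyte medians were 2.69, 2.83, 0.31 and 2.27 within the set of 5 arrays and 5.30, 6.86, 1.13 and 5.29 within the set of 2. Dntt, Psmb11, Cd3d, Lat and Rrm2 differed by 5.12, 3.698, 2.87, 2.80 and 3.22 within the set of 5 and by 11.5, 8.61, 7.205, 7.09 and 6.93 within the set of 2. Intra-abdominal array 1 carried more of these transcripts than the other 2 of its depot, with Dntt at 12.4 against 8.32 and 6.37. The adipocyte markers ran the other way, with a median difference of -6.94. Without intra-abdominal array 2 the adjusted p was 0.103 for Rrm2, 0.173 for Cd3d, 0.150 for Lat and 0.148 for Psmb11, and these calls also ended without paracardial arrays 1, 2 and 3 each. The B cell list lost its call without paracardial array 3 (0.057) or 4 (0.143) or intra-abdominal array 1 (0.083) or 3 (0.169), within the 5 arrays of the lower ceiling (0.414) and with the array set as a block (0.069).

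**Figure D2:**
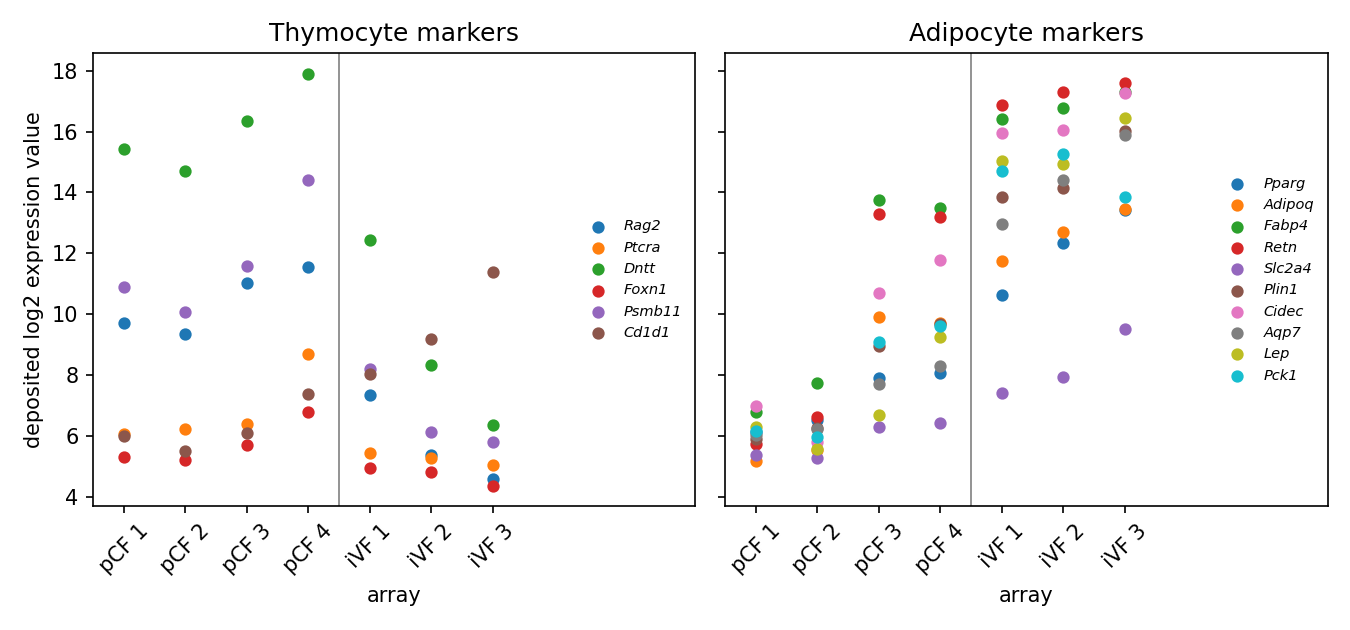
Deposited log2 values (y axis) of the 6 measured genes of the thymocyte list (left) and the 10 measured adipocyte markers (right) on each array (x axis), with 1 colour per gene. Paracardial fat is pCF and intra-abdominal fat iVF. Psmb11 in the left panel is a gene of thymic epithelium. The median adipocyte marker lies between 6.08 and 9.64 on the 4 pCF arrays and between 14.3 and 16.0 on the 3 iVF arrays, and the thymocyte gene Dntt between 14.7 and 17.9 on pCF arrays against 6.37 to 12.4 on iVF arrays.

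Mesothelial, immune and interferon lists showed few differences beyond these. Of 8 mesothelial markers 2 were higher (2 adjusted over the list alone), the keratins Krt18 and Krt8, which other simple epithelia also express, and the list gave an adjusted p of 0.740 (median -0.01, mean 1.15). Wt1, a mesothelial transcription factor, was not analysed here. Of 10 interferon response genes Usp18 was higher (1.76 ± 0.39, adjusted p = 0.040; list adjusted p = 0.891; 1 higher, adjusted over the list alone), and it passed in 1 of the 7 fits that left out an array, with 0.137 without intra-abdominal array 2. No gene passed among 7 neutrophil and mast cell markers (S100a9 0.77, 0.312; list 0.704), 6 genes of antigen presentation (H2-Eb1 1.28, 0.545; list 0.576) or 8 cytokines and chemokines (Ccl11 -1.80, 0.416; list 0.278), over all genes or adjusted over the list alone. Of 11 macrophage markers 1 was lower (1 adjusted over the list alone), Lyve1, which lymphatic endothelium also carries (-3.29 ± 0.69, 0.034; 0.135 without intra-abdominal array 2). The macrophage list was lower (median -1.70, adjusted p = 0.00057), with adjusted p = 0.419 with an estimated correlation, adjusted p = 0.195 with fry and adjusted p = 0.09996 without intra-abdominal array 3, where the median was -0.18. It was -0.75 within the set of 5 arrays and -1.80 within the set of 2.

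Vessel, matrix, complement and Wnt and BMP lists were lower in paracardial fat by camera, though not with an estimated correlation (adjusted p = 0.303 for each). Of 7 endothelial markers 3 were lower (7 adjusted over the list alone), with a median of -2.38, among them the junction protein Cdh5 (-7.05 ± 0.94, adjusted p = 0.012) and the VEGF receptor Kdr (-4.78 ± 0.81, 0.019). Of 11 extracellular matrix genes 3 were lower and 1 higher (7 lower and 1 higher, adjusted over the list alone), with a median of -1.54. Thbs1 (-4.73 ± 0.91, 0.026) and fibronectin, Fn1 (-4.44 ± 0.75, 0.019), were lower, while tenascin C, Tnc, named after its values were seen, was higher (3.45 ± 0.44, 0.011). Of 9 complement genes 4 were lower (7 adjusted over the list alone), with a median of -2.69, among them C4b (-5.54 ± 1.08, 0.027) and C6 (-4.22 ± 0.35, 0.0067). Of 10 Wnt and BMP signalling genes 3 were lower (3 adjusted over the list alone), with a median of -0.99, led by Fzd4 and the BMP antagonist Chrdl1 (-5.93 ± 0.80, 0.012).

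No gene passed over all genes among 8 smooth muscle and pericyte markers (2 lower, adjusted over the list alone; median -0.80; Acta2 -4.40, adjusted p = 0.055) or 5 fibroblast and progenitor markers (2 lower, adjusted over the list alone; median -1.32; Lum -2.94, 0.110). The list tests gave adjusted p = 1.0e-06 for endothelium, 3.9e-05 for matrix, 9.5e-07 for complement, 0.00013 for Wnt and BMP, 0.0013 for smooth muscle and 0.059 for fibroblasts. Without intra-abdominal array 3 the medians were -1.58 for endothelium, -0.97 for matrix, -1.64 for complement, -0.27 for smooth muscle and -0.66 for fibroblasts. The smooth muscle median was -0.34 within the set of 5 arrays and -1.49 within the set of 2, and the Wnt and BMP median -1.05 and -0.48. With an estimated correlation smooth muscle had adjusted p = 0.387 (0.106 with fry) and fibroblasts adjusted p = 0.564. The fibroblast list passed without paracardial array 4 (0.043) or intra-abdominal array 1 (0.032) or 2 (0.029). The adipocyte markers moved the same way as these groups (median -6.94) and the thymocyte markers the other way (3.11). Cdh5, C6 and Chrdl1 were past the threshold whichever array was left out. Without intra-abdominal array 2 the adjusted p was 0.086 for Thbs1, 0.055 for Fn1, 0.059 for Kdr and 0.107 for C4b, and these calls also ended without paracardial array 1 or 2.

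Positional, clock and stress genes gave single differences. Of 4 measured posterior Hox genes Hoxc8 was lower (-5.20 ± 0.98, adjusted p = 0.025), with paracardial values of 4.04 to 4.30 against 7.45, 8.72 and 11.92, and it differed by -3.88 and -7.88 within the sets of 5 and 2 arrays. Its call ended without intra-abdominal array 2 (0.083) or any 1 of the 4 paracardial arrays. None of 4 anterior Hox genes (Hoxc4 -0.82, 0.106) and none of 2 cardiac and thoracic transcription factors (Gata6 -0.73, 0.093) passed over all genes. Adjusted over the list alone, 1 posterior Hox gene, no anterior Hox gene and 1 of the transcription factors were lower. Of 9 circadian clock genes 2 were lower (2 adjusted over the list alone), the repressor Nr1d1 (-4.54 ± 0.52, 0.0087) and Clock (-3.07 ± 0.39, 0.011). The clock list was lower (median -0.43, adjusted p = 0.013), with adjusted p = 0.371 with an estimated correlation and adjusted p = 0.060 without paracardial arrays 1 and 2. The clock list passed in 19 of 22 alternatives. Its median was -0.16 without intra-abdominal array 1 and -0.66 without array 3, and -0.57 within the set of 5 arrays against -0.072 within the set of 2. Of 15 immediate early and heat shock genes the phosphatase Dusp1 was lower (-2.85 ± 0.46, 0.018; 0.078 without intra-abdominal array 2; 1 adjusted over the list alone), and the list did not differ (adjusted p = 0.429). None of 3 steroid handling genes passed over all genes (2 lower, adjusted over the list alone; Sult1e1 -2.58, 0.073).

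Markers of heart and skeletal muscle, lung, epididymis and testis, pancreas and nerve did not pass, over all genes or adjusted over the list alone. The largest member differences were 0.40 for Actn2 among 3 cardiomyocyte markers (adjusted p = 0.470), 0.67 for Actn3 among 2 skeletal muscle markers (0.149), -0.98 for Napsa among 2 lung markers (0.571) and -1.81 for Prm2 among 2 epididymis and testis markers (0.542). Prm2, a sperm protamine, read 10.6 on intra-abdominal array 2 and 4.08 to 5.42 on the other 6 arrays. Napsa read 10.3 on intra-abdominal array 1 and 6.19 to 7.54 on the other 6 arrays. Cela1 differed by -0.47 among 2 pancreas markers (0.479) and Npy by 0.11 among 3 nerve markers (0.909). These lists held fewer than 5 measured genes and were not tested as lists.

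**Figure D3:**
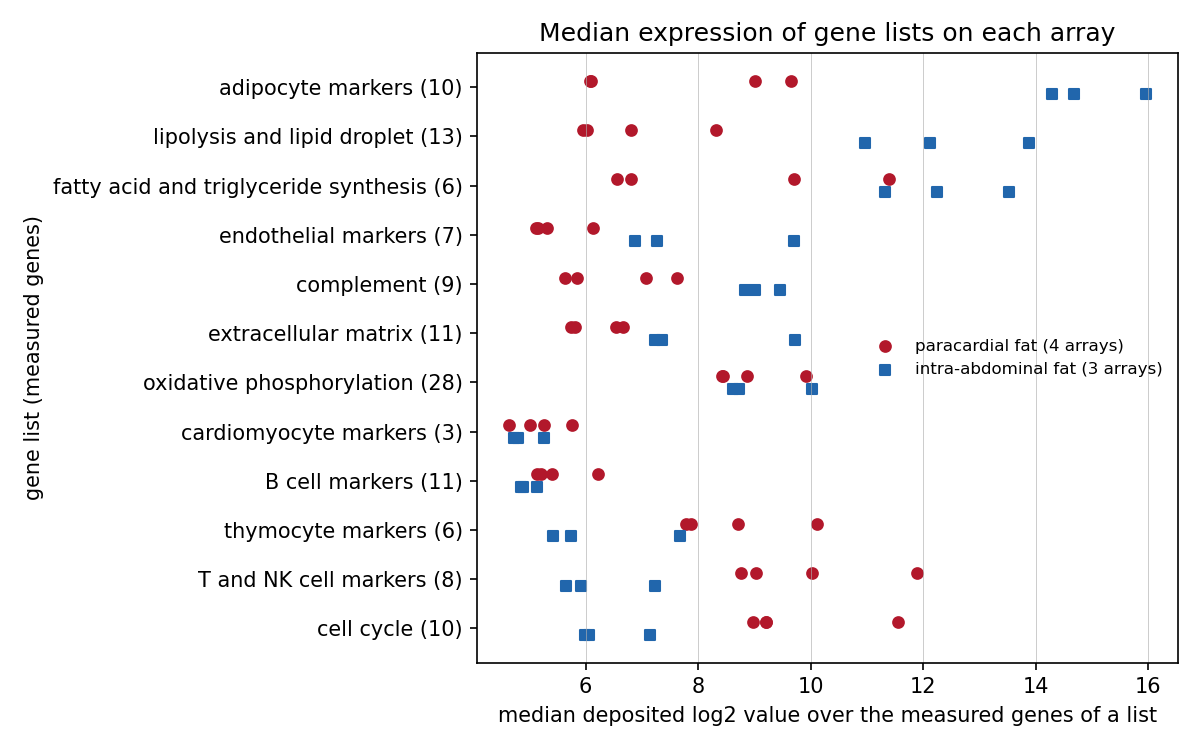
Median deposited log2 value (x axis) over the measured genes of 12 gene lists (y axis, number of genes in brackets). Red circles are the 4 paracardial arrays and blue squares the 3 intra-abdominal arrays; cell cycle medians are 8.97 to 11.5 on paracardial arrays and 5.99 to 7.14 on intra-abdominal arrays, while the cardiomyocyte medians overlap.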

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

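Every test in this part except the share of genes in which intra-abdominal array 1 stood above the other 2 of its depot, and the splits of the arrays for the number of lists, was chosen after the result was seen. A paracardial array stood far from the other 3 in 5 of 114 values tested, 4 of them in array 4, where chance gives about 1 in 20; groups of 3 arrays were not tested. Ucp1 read 13.918 on paracardial array 4 against 4.611 to 6.138 on the other 3. Hmgcs1 read 10.694 on array 4 against 8.583 to 8.756. Clock read 8.414 on array 1 against 8.827 to 8.878. The median of the beige fat markers was 6.6441 on array 4 against 5.9518 to 6.0228. The median of the cell cycle genes was 11.547 on array 4 against 8.975 to 9.2074.

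Paracardial samples combined high T cell and cell cycle genes, and 3 of 6 genes of the thymocyte list (among them the epithelial Psmb11), with low adipocyte genes. The pattern was not removed by 3 other scalings, over which the smallest of the thymocyte and adipocyte median differences was 2.8667 in size. These scalings started from the deposited values, so the scaling before deposit and the ceiling were not tested. A lymph node without thymus as the whole source cannot be judged by a count on a list written after the values were seen. On it, 10 of 13 measured thymic epithelial genes (6 of the 9 in no fixed list) had all paracardial arrays above all intra-abdominal arrays. The share was 17.9% over all tested genes (binomial p = 5.8e-06 and 0.0017, with genes taken as independent). Among these hits Krt14 read 5.73 and 5.96 on paracardial arrays 3 and 4, below the array medians of 6.26 and 6.37. Camera with an estimated correlation (0.199) did not call this list (adjusted p = 0.171). Thymic tissue in the paracardial samples may account for the pattern. Of 10 measured thymocyte and thymic epithelial genes that no fixed list holds, 7 (70%) had all paracardial arrays above all intra-abdominal arrays, against 17.9% of all tested genes and 2.86% by chance. These 10 are the 9 thymic epithelial genes in no fixed list counted above and Ly6d, so this share is not separate support. Of the 10, 4 lay above the median gene on all intra-abdominal arrays. A difference between the depots themselves, lymph node tissue with or without thymus and epithelium of another organ stay open, and no test here settles them.

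Intra-abdominal array 1 carried thymocyte genes above the other 2 of its depot. A paracardial sample under the wrong label is argued against, since 10 of 10 adipocyte markers on this array lay above all 4 paracardial arrays. Paracardial RNA in this sample cannot be told apart from other sources: among the 581 genes higher in paracardial fat, array 1 stood above both others in 42.857%, against 35.165% of genes not past the threshold, a gap between the limits set beforehand. No biological explanation was tested.

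Adh1 was lower in paracardial fat by 4.61 on the log2 scale, less than the adipocyte markers. A smaller share of fat tissue in the paracardial samples may account for it. The median difference of the 10 adipocyte markers was -6.942, further below 0 than that of Adh1. This order alone cannot decide, since Adh1 started lower in intra-abdominal fat (mean 11.37, adipocyte medians 14.3 to 16.0). It read 5.28 to 7.77 on paracardial arrays, so low values left it less room to fall. On paracardial arrays 1 and 2 the adipocyte median (6.08 and 6.09) lay near the median of the array (6.07 and 6.005) and is not shown to be above background, so Adh1 cannot be compared per adipocyte there. On paracardial arrays 3 and 4 Adh1 minus the adipocyte median was -1.25 and -2.11, against -3.76, -4.13 and -2.91 on intra-abdominal arrays 1 to 3. Relative to these markers Adh1 was thus not lower on those 2 paracardial arrays, on a scale that is not calibrated. A difference in Adh1 within the adipocytes of the depots was not tested and stays open.

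Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, gave as many genes (851, with 1 gene in the highest other split). Chance is thus argued against for the number of genes. It is not excluded, since 1 of 35 is the smallest share that these splits can give and the samples are taken as independent. For the number of lists, 3 of 35 splits gave as many as the real 20, with 20 in the highest other split (paracardial array 4 with the 3 intra-abdominal arrays), so chance cannot be excluded.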

How the results depend on the processing

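The array set, the 5 arrays of the lower ceiling, the removal of paracardial arrays 1 and 2 and the removal of ceiling genes were chosen after the data were seen. Against 851 genes (581 higher, 270 lower), quantile normalization applied again gave 416 lower and cyclic loess 530 lower. Array weights, whose estimation stopped before convergence, gave 3614 genes (2235 higher, 1379 lower). The array set as a block gave 1654 (1081 higher, 573 lower). Without paracardial arrays 1 and 2, 1 gene passed (0 higher, 1 lower). Leaving out single arrays gave 185 to 833 genes (114 to 569 higher, 62 to 274 lower) and 15 to 22 lists against 20. The other alternatives stayed within 1.5 times of each count, but did not call all the same genes. Shared with the 851 were 603 of 848 after quantile normalization, 709 of 1042 after cyclic loess and 574 of 936 within the 5 arrays of the lower ceiling. No shared call had the opposite sign, which the lack of overlap fixes where arrays are only left out. With the replicate number as a block, limma gave 0 genes (0 higher, 0 lower, and 2134 at an unadjusted p under 0.05) with 2 residual degrees of freedom in place of 5, and Adh1 differed by -4.87. With this block camera called 19 lists, as 3 list calls were lost and 2 were gained. Deviations of same-numbered arrays correlated at 0.048, 0.047 and -0.50, and no array correlated best with the array of its own number. This gives no sign of pairing by number and does not rule out shared animals. Adh1 lost its call within the 5 arrays of the lower ceiling (-4.03) and without paracardial arrays 1 and 2 (-3.72), and ranged from -5.03 to -3.77 without single arrays; over 20 alternatives its adjusted p was 0.00079 to 0.142. The cause of these changes was not tested. The 5 arrays of the lower ceiling gave 936 genes and the 5 left without paracardial arrays 1 and 2 gave 1, so the number of arrays alone does not set the count. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.303, 1 at an unadjusted p under 0.05), fry called 14, and 15 of the 20 lists passed without any single array. List medians also moved over 22 alternatives, from -6.56 to -2.57 for lipolysis and from -2.49 to -0.74 for Wnt and BMP signalling. The B cell list also lost its call without the dimmest 25% of genes and with array weights, and the beige list with quantile normalization and with array weights. Of 53 named genes past the threshold, 24 passed without any single array. None changed sign (0 genes), which again the lack of overlap fixes where arrays are only left out. Signal over background is unknown for these values and limits what low values can show.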

Other observations

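The families in this part were chosen after the data were seen, and the direction of each held under the 3 other scalings. Histone genes, the packaging proteins made during DNA replication, were higher in paracardial fat in 18 of 30 cases and lower in 0, with a median difference of 2.39 (1.99 to 2.26 under the other scalings). T cell receptor segments were higher in 24 of 115 cases (27 to 37 under the other scalings) and lower in 0, with a median of 1.52, and immunoglobulin segments in 21 of 192 and 0, with a median of 2.16. Ribosomal protein genes were higher in 79 of 156 cases and lower in 0, with a median of 2.19; 135 of these carry pseudogene symbols, so the copies that gave the signal are uncertain, and 38 were higher after quantile normalization. Kinesins were higher in 3 of 14 cases (5 to 6 under the other scalings) and replication genes in 4 of 22 (6 to 8), while solute carriers were lower in 9 of 122 cases (9 to 14) and higher in 2 (1 to 2). None of 6 collagens passed (median -0.86).

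Of the lists added after the data were seen, the wider thymocyte list had 5 of 9 genes higher (9 adjusted over the list alone, median 4.34). The thymic epithelial list had 6 of 13 higher (9 higher and 1 lower adjusted over the list alone, median 1.46), and none of 3 lymph node stromal genes passed (median 0.34). Camera with an estimated correlation gave adjusted p = 0.171 for the wider thymocyte and for the thymic epithelial list. Ly6d, an early lymphoid surface protein, differed by 4.34 (adjusted p = 0.032), the endocytic receptor Ly75 by 4.12 (0.024), the keratin Krt5 by 4.42 (0.019) and Tbata by 3.07 (0.045). Krt14 (1.46, 0.101), Epcam (1.33, 0.066) and Cldn4 (1.05, 0.105) did not pass, although all 4 paracardial arrays lay above all 3 intra-abdominal arrays. The genes Dll4 and Ctsl overlapped, and Enpep lay below (-2.35, 0.094). On intra-abdominal array 1, Psmb11 read 8.19 and Krt5 9.45, against 6.12 and 5.79, and 6.78 and 6.38, on the other 2. Of 2597 probes without a single gene symbol 144 passed, 120 higher and 24 lower in paracardial fat.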
